A study of Mus musculus with 8 samples.

How the data were processed

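RNA was sequenced from the lumbar and thoracic spinal cord of mice at postnatal day 14. Per the labels, 4 libraries came from C57BL/6J wild-type mice (WT) and 4 from a triple knockout of the Mir34a, Mir34bc and Mir449 loci (TKO), with 2 libraries for each combination of segment and genotype. RNA was extracted with a column kit and made into libraries with a stranded kit that selects polyadenylated RNA, per the labels' protocols. The labels do not say that the libraries came from separate mice, nor whether a lumbar and a thoracic library share a mouse, so p-values measure only the spread between these samples, which may be technical.

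The authors deposited 1 table per library with 41325 genes, whole-number read counts per gene and RPKM. The counts are given for exons, introns and whole genes, in total and for uniquely placed reads, per the file headers. In every table the deposited count of total gene reads equals exon plus intron reads. The deposited RPKM divides total exon reads by exon length and by a per-sample total slightly above the sum of gene reads. The genome build is mm10, per the submitters' processing notes. The aligner, the counting program, its strand setting and its read filters are not given in the sources used here. Reads from a gene and an antisense partner could therefore not be told apart, and total counts include reads that match several places.

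The main values were total gene reads. Counts were scaled with TMM factors and genes with few reads were removed with filterByExpr over the 4 groups. The remaining 17067 genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, robust fit, R 4.3.3). P-values had Benjamini-Hochberg adjustment and a threshold of 0.05. All 8 libraries entered 1 fit with a mean for each of the 4 groups, because 2 libraries per group leave few degrees of freedom alone. The common dispersion was 0.0332. Contrasts were TKO minus WT in the lumbar cord, in the thoracic cord and averaged over both, the difference of the lumbar and thoracic genotype effects, and thoracic minus lumbar within each genotype. CPM values are gene reads scaled to the TMM-adjusted library size.

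35 gene lists of cell types, pathways and label checks were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over the lists of a contrast. Each call is set beside the same test with an estimated correlation, and beside the number of members that passed when p-values were adjusted over the list alone. Matches to the shared miR-34/449 seed were searched in annotated 3' UTRs (GENCODE vM21 on GRCm38, the longest per gene) with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Genes with and without a site were compared within 10 bins of UTR length by 10000 permutations, two-sided, and set beside 200 control heptamers of the same base composition. Coordinates are those of GRCm38, which mm10 names too.

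The genes named were fixed by rule. For each genotype contrast these are up to 10 higher and 10 lower genes of largest fold among those with an adjusted p under 0.05, a mean of 1 CPM or more in the higher group and no overlap between TKO and WT libraries. Segment contrasts take 5 in each direction and the difference of genotype effects the 5 with the smallest p. Gene models with only a number or clone name are counted but not named. The genes at the deleted loci, sex-linked genes and up to 4 members of each list described, those with the smallest p, are named as well. Nnt was not analysed here. This rule, the groups, the lists, the tests and most alternatives were chosen before the data were examined.

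Alternatives tried were other size factors (RLE, upper quartile), DESeq2 1.42.0, limma-voom, limma on log2(RPKM + 0.5), no filter and a mean of 10 reads. Others were unique gene reads, a replicate block, summed libraries, fits of only 4 libraries, leaving out sex-linked and red-cell genes, and leaving out each library in turn. Exon counts, mitochondrial genes left out, the mitochondrial share as a covariate, leaving out both TKO replicate 2 libraries, leaving out genes near the deleted loci and crossed replicate numbers were added after the data had been seen.

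Libraries held 16195212 to 20907819 gene reads, of which 94.7% to 95.6% were uniquely placed. A count of 0 in a library allows up to 3 reads, or 0.153 to 0.174 CPM. Ratios of low counts carry exact 95% intervals, and these intervals and floors cover counting error only. The same-group libraries differed far beyond sampling noise (chi-square per degree of freedom 15.6 to 70.8), so none is the same library deposited again and each entered the fits once. This does not show that they came from separate mice. Tested on simulated counts drawn from the real means, the lumbar test recovered 39% of 100 genes changed by 2-fold and 99% of 100 changed by 4-fold, with 4 false calls among 16852 genes. For the contrast over both segments these shares were 86% and 100%, with 9 false calls among 16843 genes. The changed genes were drawn only from genes with many reads, so recovery at low counts was not tested. Counts were drawn independently for each gene and library. The false calls therefore do not cover structure that real libraries share across genes.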

Results

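Gene expression was measured by RNA sequencing in the spinal cord of mice lacking the microRNAs of the miR-34/449 family and of C57BL/6J mice. These microRNAs share a seed sequence and are known from the p53 response and from the development of multiciliated cells. The title of the series places the work in the study of spinal muscular atrophy, a motor neuron disease caused by loss of SMN protein. Total gene reads were 19749083 and 16195212 in the lumbar TKO libraries and 17827821 and 18826059 in lumbar WT. They were 18952400 and 17438480 in thoracic TKO and 20907819 and 18601575 in thoracic WT. Between 21685 and 22114 genes had reads in a library. Mitochondrially encoded transcripts took 12% and 4.99% of reads in lumbar TKO replicates 1 and 2 and 10.5% and 12.4% in lumbar WT. They took 11.9% and 6.53% in thoracic TKO and 16.8% and 9.45% in thoracic WT. Intron reads made up 6.23% and 6.69% in the TKO replicate 2 libraries of the lumbar and thoracic cord and 4.39% to 5.22% in the other 6 libraries.

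**Figure D1:**
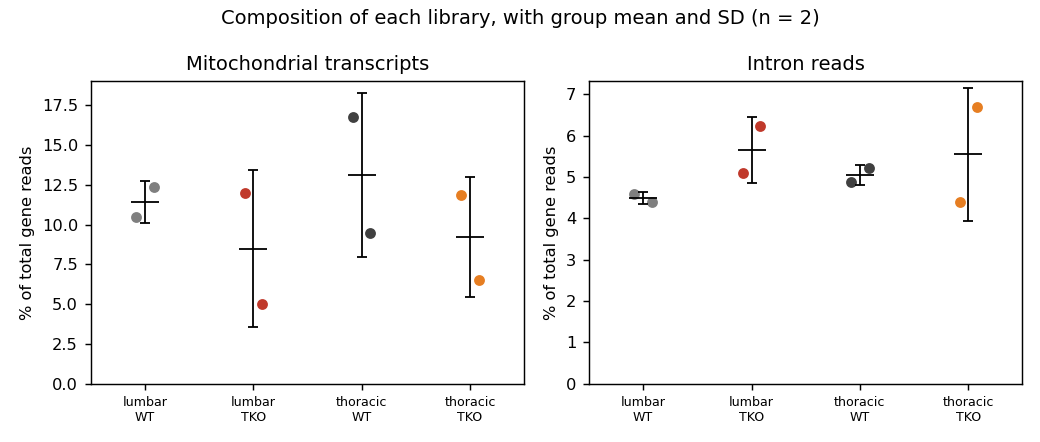
Percent of gene reads from mitochondrially encoded genes and from introns in each of the 8 libraries (points, by group). The TKO replicate 2 libraries have the lowest mitochondrial shares, 4.99% and 6.53%, and the highest intron shares, 6.23% and 6.69%.

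The deleted loci were examined first. The precursors Mir34a (chromosome 4, 150068454 to 150068555), Mir34b, Mir34c, Mir449a, Mir449b and Mir449c had 0 reads in all 8 libraries, of either genotype. Libraries of polyadenylated RNA do not capture such precursors, so this checks no label. Gpx8, a peroxidase of the endoplasmic reticulum, lies inside the Mir449 region (chromosome 13, 113042753 to 113046410). It fell from 16.9 ± 2.8 CPM in WT to 6.50 ± 1.08 CPM in TKO (SD over the 4 libraries of a genotype, 2 per segment), a log2 fold change of −1.38 (SE 0.183, adjusted p = 0.0254). Cdc20b, the host gene of Mir449 (chromosome 13, 113035111 to 113091195), had 52 reads in TKO and 3 in WT, a ratio of 18.1 (95% counting interval 5.87 to 90.7), with an adjusted p of 0.0611. Gm37795, a transcript model overlapping Mir34a (chromosome 4, 150068539 to 150070997) that was singled out after its values were seen, rose from 8.21 ± 1.66 to 37.4 ± 5.59 CPM (adjusted p = 0.00264). Ccno (log2 0.74, adjusted p = 0.432) and 4833427G06Rik, also known as Hoatz (0.04, 0.975), did not pass. Mcidas, with 9 TKO and 6 WT reads, and Btg4, with 1 and 3, were too low to test. Xist and Tsix had 0 to 3 reads per library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 8 libraries, at adjusted p of 0.354, 0.68, 0.867 and 0.566 between genotypes.

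The mean genotype difference over both segments asked what loss of the family changes in the cord as a whole. Igf1, the growth factor that promotes survival and myelination (chromosome 10, 87858265 to 87937042), fell 3.82-fold, from 20.4 ± 2.32 CPM in WT to 5.31 ± 0.724 in TKO (SD, n = 4 libraries each; log2 −1.94, SE 0.146, adjusted p = 0.00158). Lum, the matrix proteoglycan lumican made by meningeal fibroblasts (chromosome 10, 97565128 to 97572703), fell 3.24-fold, from 11.3 ± 3.11 to 3.38 ± 0.58 CPM (log2 −1.70, SE 0.164, adjusted p = 0.00471). Masp2, a protease of the lectin pathway of complement (chromosome 4, 148602554 to 148615499), rose from 0.412 ± 0.111 to 5.12 ± 0.23 CPM (log2 3.64, SE 0.227, adjusted p = 0.00049). Padi2, which citrullinates myelin basic protein (chromosome 4, 140906344 to 140952586), rose from 113 ± 10.7 to 245 ± 40.1 CPM (log2 1.11, SE 0.104, adjusted p = 0.00421). Fam107a, an actin-associated protein abundant in astrocytes, rose from 38.4 ± 6.35 to 109 ± 19.2 CPM (log2 1.51, SE 0.17, adjusted p = 0.0138). Etnppl, an astrocytic phospholipid enzyme, rose from 0.803 ± 0.16 to 3.33 ± 1.09 CPM (log2 2.06, SE 0.303, adjusted p = 0.0356). Dao, the oxidase of D-serine, rose by 1.80 on the log2 scale (SE 0.214, adjusted p = 0.0189).

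**Figure D2:**
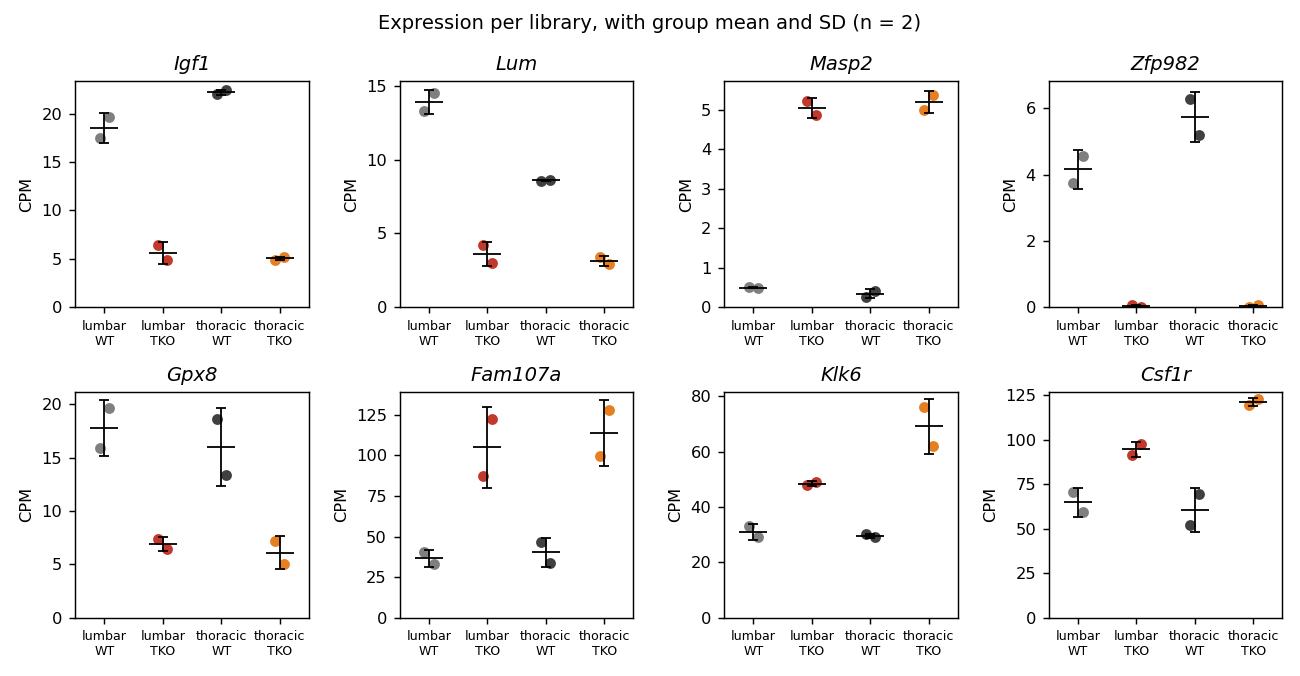
CPM of 8 genes in each library (points), with group mean and SD (n = 2 libraries), in lumbar and thoracic TKO and WT; linear axes from 0. Igf1 lies at 5.59 and 5.02 CPM in the TKO groups and at 18.5 and 22.2 CPM in the WT groups.

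In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 61 of 17067 genes, 38 higher and 23 lower in TKO. At an unadjusted p under 0.05 there were 3254 genes, against 853 expected with no effect, and the median SE was 0.169. Of the other named genes, Samd11 rose from 0.906 ± 0.243 to 6.84 ± 1.72 CPM (log2 2.94), Col20a1, a collagen, by 1.18 and Ppp1r1b, the phosphatase inhibitor DARPP-32, by 1.13, with adjusted p of 0.00264, 0.0254 and 0.0437. Slc26a7, an anion exchanger, fell by 1.92 on the log2 scale (adjusted p = 0.0249), and Ear1, an eosinophil-type ribonuclease, by 3.31 (0.0375). Rsg1, a GTPase needed for cilia, fell by 1.68 (adjusted p = 0.0346). Tnfrsf8, the receptor CD30, had 8 reads in TKO and 98 in WT (adjusted p = 0.0216). Hba-a2, an alpha globin, fell by 1.96 (adjusted p = 0.0356) with only 6.71% of its reads uniquely placed, so its count is shared with its copies. Leaving out 1 library gave 194 calls without lumbar TKO replicate 1, 45 (20 higher, 25 lower) without lumbar TKO replicate 2, 9 and 7 without lumbar WT replicates 1 and 2, 11 and 12 without thoracic TKO replicates 1 and 2, and 12 and 11 without thoracic WT replicates 1 and 2. Without both TKO replicate 2 libraries the balance of directions turned, with 23 genes higher and 61 lower among 84 calls, of which 32 were among the 61 called with all libraries. Igf1, Masp2, Zfp982, Samd11 and Zfp981 passed in all 8 of these fits. Lum passed in 7 (not without lumbar WT replicate 2), Padi2 in 6 (not without lumbar WT replicate 1 or 2), Fam107a in 4 and the other genes named here, Etnppl and Dao included, in 1 to 3.

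A cluster of KRAB zinc finger genes, which encode DNA-binding repressors, went both ways. Zfp982 (chromosome 4, 147492417 to 147513486) fell, with 2 reads in TKO and 377 in WT, a WT over TKO ratio of 180 (95% counting interval 49.6 to 1490, adjusted p = 0.00049). Zfp990 rose, with 205 reads in TKO and 4 in WT (ratio 53.6, 20.6 to 199, adjusted p = 0.0356). Zfp979 fell by 3.22 and Zfp984 by 1.90 on the log2 scale (adjusted p = 0.0437 and 0.0359). Zfp981 (chromosome 4, 146502027 to 146539395) rose from 6.31 ± 0.435 to 21.9 ± 2.43 CPM of gene reads (adjusted p = 0.00199), but its log2 change was −0.06 in exon-based RPKM (adjusted p = 0.641 with limma). These genes have near-identical copies. Of the reads of Zfp982, Zfp990, Zfp979, Zfp984 and Zfp981, 98.7%, 78.5%, 75.2%, 49.5% and 72.0% were uniquely placed, so the values of the last 4 are uncertain. Within 10 Mb of Mir34a, 11 of 211 tested genes were called (5.21%; 6 higher, 5 lower), against 50 of 16856 elsewhere (0.297%), an odds ratio of 18.5 (95% interval 8.54 to 36.6, two-sided Fisher's exact p = 1.93e-10). The 11 are Masp2, Padi2, Samd11, Tnfrsf8, Rsg1, the 5 zinc finger genes and Gm37795. They are neighbours on 1 chromosome and some are copies, so they are not independent as Fisher's test assumes. Its interval is then too narrow and its p too small. Near Mir34b and Mir34c none of 233 tested genes was called, and near Mir449 1 of 75, Gpx8 (Fisher's exact p = 0.236).

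**Figure D3:**
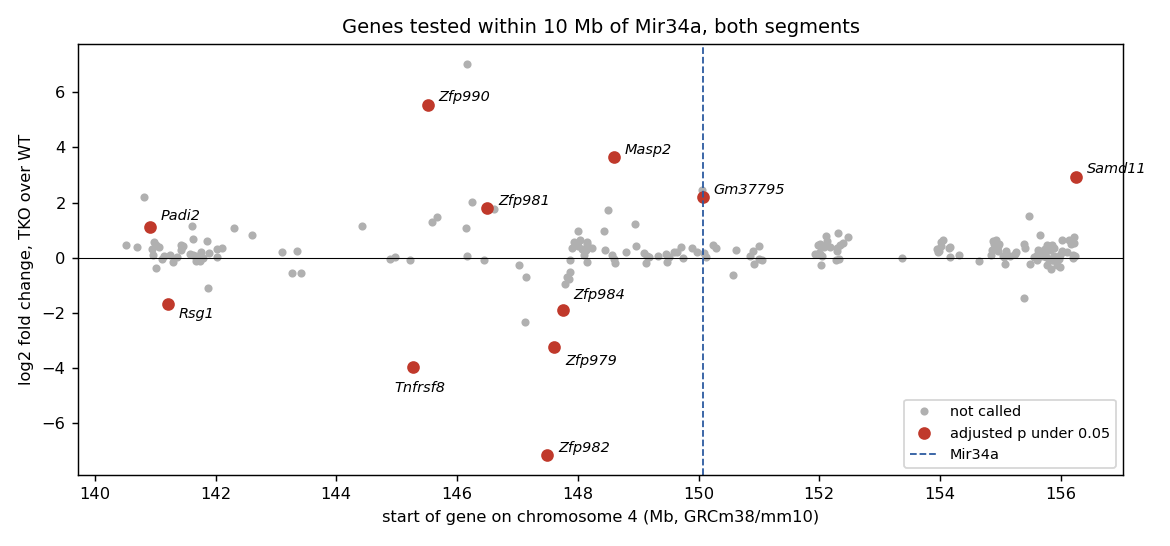
Log2 fold change TKO over WT, both segments, of tested genes within 10 Mb of Mir34a (dashed line) by gene start on chromosome 4 (Mb, GRCm38); genes past the adjusted p threshold are red and named. Of 211 genes, 6 passed as higher and 5 as lower.

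Genes of myelinating oligodendrocytes rose in TKO as a group, with a median log2 change of 0.413 over 25 genes (24 above 0; camera adjusted p = 1.85e-09, adjusted p = 0.0729 with an estimated correlation). Klk6, a myelin-associated protease, rose (log2 0.93, SE 0.118, adjusted p = 0.0228). So did Opalin, a paranodal membrane protein (0.80, SE 0.111, 0.0304), and Hapln2, a link protein of nodes of Ranvier (0.90, SE 0.146, 0.0466). Adjusted over the list alone, 17 genes passed as higher. Gjb1, the gap junction protein connexin 32, had a log2 value of 0.55 (adjusted p = 0.0772). Microglial genes rose with a median of 0.373 over 24 genes (camera adjusted p = 0.000118, adjusted p = 0.286 with an estimated correlation). Csf1r, the receptor that sustains microglia (0.77, SE 0.126, adjusted p = 0.0493), and the protease Ctss (0.76, SE 0.123, 0.0458) rose, and adjusted over the list alone 12 were higher and 1 lower. Astrocyte genes rose with a median of 0.328 over 24 genes (adjusted p = 0.000129, adjusted p = 0.286 with an estimated correlation). Of them 9 were higher when adjusted over the list alone and 1 over all genes, Itih3 (0.99, SE 0.109, adjusted p = 0.0126). Aldoc (0.64) did not pass over all genes (adjusted p = 0.0772). Ependymal and motile cilia genes, 31 of 39 of them above 0, rose with a median of 0.233 (adjusted p = 0.00249, adjusted p = 0.286 with an estimated correlation). No member passed, even adjusted over the list alone; Foxj1, their master regulator, had a log2 value of 0.62 (adjusted p = 0.19). In the thoracic cord alone the list had a median of 0.0081, with 20 genes above and 19 below 0 (adjusted p = 0.532), against 0.296 in the lumbar cord.

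The genes of meningeal fibroblasts fell in TKO, with a median of −1.28 and 20 of 20 below 0 (camera adjusted p = 7.93e-12, adjusted p = 0.323 with an estimated correlation). Lum and Dcn, the proteoglycan decorin (log2 −1.40, SE 0.204, adjusted p = 0.0346), fell, and 17 genes were lower when adjusted over the list alone. Igf2, a fetal growth factor (−1.62, adjusted p = 0.0512), did not pass over all genes. Cell cycle genes fell with a median of −0.713 and 28 of 29 below 0 (adjusted p = 2.74e-13, adjusted p = 0.323 with an estimated correlation). None of them passed over all genes tested and 24 were lower when adjusted over the list alone, such as Nusap1 (−1.05, adjusted p = 0.0734) and the proliferation marker Mki67 (−0.96, 0.0791). With the mitochondrial share as a covariate, added after the data had been seen, the medians were 0.420 for oligodendrocyte, 0.377 for microglial, 0.248 for astrocyte, −1.71 for fibroblast and −0.573 for cell cycle genes. Blood genes, 6 of 13 above 0 and 7 below, fell at the preset correlation with a median of −0.836 (adjusted p = 0.00509, adjusted p = 0.826 with an estimated correlation; 6 lower when adjusted over the list alone). Their median was −0.447 without lumbar TKO replicate 1 (adjusted p = 0.771), −1.58 without lumbar TKO replicate 2 and −0.327 without lumbar WT replicate 1. Mitochondrially encoded genes fell with a median of −0.629 over 13 (adjusted p = 0.00154, adjusted p = 0.826 with an estimated correlation; 1 lower when adjusted over the list alone); with the covariate their median was −0.0924 (adjusted p = 0.217), and without both TKO replicate 2 libraries −0.148 (0.46). It was −1.03 without lumbar TKO replicate 1, −0.361 without lumbar TKO replicate 2 and −0.324 without thoracic WT replicate 1.

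**Figure D4:**
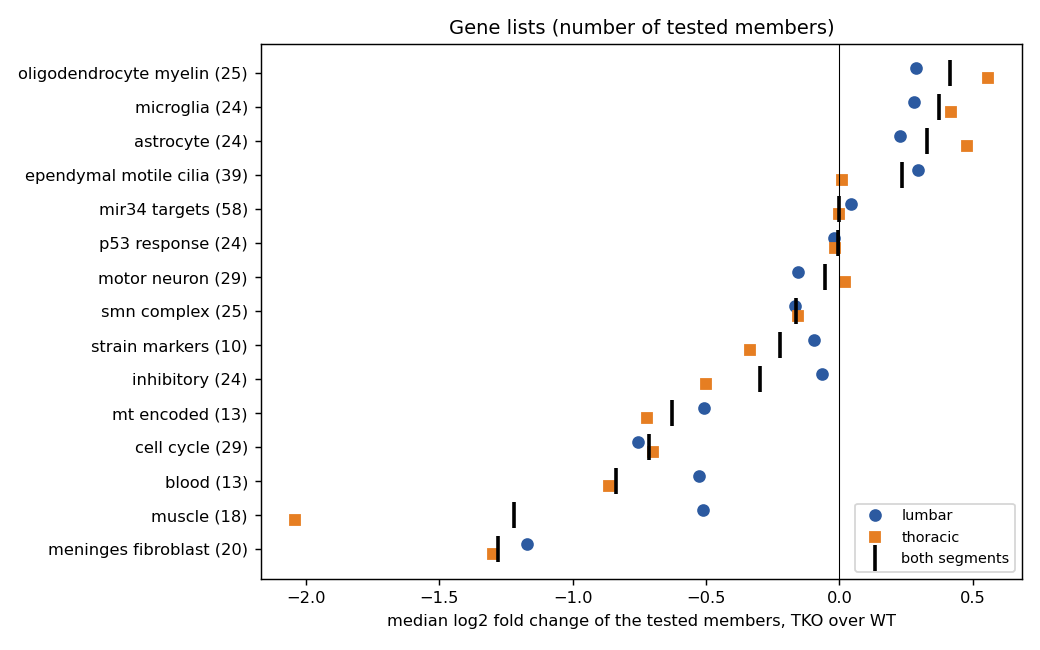
Median log2 fold change TKO over WT of the tested genes of 15 lists, in the lumbar cord (circles), the thoracic cord (squares) and both segments (bars). Meningeal fibroblast (−1.28) and cell cycle (−0.713) genes lie below 0, and oligodendrocyte (0.413), microglial (0.373) and astrocyte (0.328) genes above.

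Genes of inhibitory transmission fell, with a median of −0.299 over 24 (camera adjusted p = 0.00524, adjusted p = 0.286 with an estimated correlation). Adjusted over the list alone 1 was higher and 5 lower, such as Gabra5, a GABA receptor subunit (−0.75, adjusted p = 0.0594), and Glra2, a fetal glycine receptor subunit (−1.02, 0.0765). Muscle genes fell at the preset correlation (median −1.22, 15 of 18 below 0, adjusted p = 0.042, adjusted p = 0.826 with an estimated correlation). The 1 member that passed, the glycogen phosphorylase Pygm, which astrocytes also express, rose by 0.80 on the log2 scale (SE 0.123, adjusted p = 0.0375). The muscle call was lost without lumbar TKO replicate 1 (adjusted p = 0.133), lumbar WT replicate 1 (0.134), thoracic TKO replicate 2 (0.107) or thoracic WT replicate 1 (0.13, median −0.389), with the mitochondrial share as a covariate (0.339) and without both TKO replicate 2 libraries (0.154). Genes that differ between inbred strains fell (median −0.222 over 10, adjusted p = 0.0223, adjusted p = 0.286 with an estimated correlation; 1 lower when adjusted over the list alone), but not without lumbar TKO replicate 1 (adjusted p = 0.119) or thoracic TKO replicate 1 (0.0955), and with a median of −0.121 without thoracic WT replicate 1. In the lumbar cord alone the inhibitory, strain and muscle lists had adjusted p of 0.162, 0.208 and 0.464. The SMN complex and its snRNP partners had a median of −0.163 over 25 genes (adjusted p = 0.0973), with 1 lower when adjusted over the list alone, Lsm11 of the U7 snRNP (−0.60, SE 0.107, adjusted p = 0.0573). Smn1, the gene lost in spinal muscular atrophy, had a log2 value of −0.06 (SE 0.131, adjusted p = 0.808). Motor neuron genes had a median of −0.05 (adjusted p = 0.53) and p53 response genes one of −0.00494 (adjusted p = 0.793). Published miR-34 targets, 58 tested, split into 29 above and 29 below 0 (adjusted p = 0.946). Csf1r passed as higher, and adjusted over the list alone 1 was higher and 2 lower, Gas1 (−0.67) and Dtl (−1.22).

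The remaining lists were not called over both segments. Their camera adjusted p was 0.114 for glutamatergic genes, 0.182 for stress and hypoxia, 0.277 for rostral Hox, 0.308 for oligodendrocyte precursor, 0.323 for immediate early, 0.355 for neuromuscular junction and 0.416 for both Schwann and interferon genes. It was 0.427 for cholesterol synthesis, 0.548 for sex-linked, 0.616 for sensory ganglion, 0.663 for both endothelial and synaptic vesicle, 0.774 for ribosomal protein and 0.775 for nuclear respiratory chain genes. It was 0.814 for both the deleted loci and neurofilament genes, 0.904 for potassium and sodium channels, 0.908 for adipose and bone and 0.946 for caudal Hox genes. Among their members Cdh19 of Schwann cell precursors rose (log2 0.90, SE 0.143, adjusted p = 0.0437), and the NMDA receptor subunit Grin2c had a log2 value of 1.14 (adjusted p = 0.0512).

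In the lumbar cord alone, TKO against WT, Igf1 fell from 18.5 ± 1.55 to 5.59 ± 1.1 CPM (SD, n = 2 libraries each; log2 −1.73, SE 0.206, adjusted p = 0.0352) and Lum from 13.9 ± 0.822 to 3.61 ± 0.833 CPM (−1.95, SE 0.23, 0.0352). Zfp982 fell, with 1 read in TKO and 153 in WT (ratio 152, counting interval 26.9 to 6060, adjusted p = 0.011). Masp2 rose by 3.35 on the log2 scale (SE 0.313, adjusted p = 0.011) and Zfp981 by 1.81 (SE 0.207, 0.0352; −0.12 in exon-based RPKM). Cell cycle genes fell as a group, 29 of 29 below 0 with a median of −0.756 (camera adjusted p = 5.26e-17, adjusted p = 0.438 with an estimated correlation), though 0 members passed even when adjusted over the list alone. So did fibroblast genes (median −1.17, 19 of 20 below 0, adjusted p = 3.16e-12, adjusted p = 0.438 with an estimated correlation; 8 lower when adjusted over the list alone; median −0.772 without lumbar TKO replicate 1 and −0.702 without lumbar WT replicate 1). Ependymal and motile cilia genes rose (median 0.296, 35 of 39 above 0, adjusted p = 3.18e-07, adjusted p = 0.193 with an estimated correlation; 0 passed when adjusted over the list alone). Oligodendrocyte genes rose too (0.287, adjusted p = 3.18e-07, adjusted p = 0.126 with an estimated correlation; 2 higher when adjusted over the list alone).

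At the preset correlation, microglial (median 0.281) and astrocyte genes (0.228) also rose in the lumbar cord, both with an adjusted p of 0.00283 (adjusted p = 0.438 and 0.526 with an estimated correlation). Ribosomal protein genes fell (median −0.24, 44 of 48 below 0, adjusted p = 3.17e-05), as did mitochondrially encoded (−0.506, 0.00222), motor neuron (−0.155, 22 of 29 below 0, 0.00978), blood (−0.526, 0.0145) and SMN complex genes (−0.168, 0.0145). With an estimated correlation the adjusted p was 0.684 for the first 4 of these and 0.606 for SMN complex genes. Adjusted over the list alone, 1 astrocyte gene was higher and 2 blood genes lower, and 0 members passed of the microglial, ribosomal protein, mitochondrially encoded, motor neuron and SMN complex lists. Without both TKO replicate 2 libraries the adjusted p was 0.137 for microglial, 0.0582 for astrocyte, 0.773 for mitochondrially encoded and 0.0652 for SMN complex genes; for the last 2 it was 0.333 and 0.14 with the mitochondrial share as a covariate. All 7 of these lists lost their call without some library. Without lumbar TKO replicate 1 the adjusted p was 0.365 for blood, 0.528 for motor neuron, 0.109 for ribosomal protein and 0.0757 for SMN complex genes. Without lumbar TKO replicate 2 it was 0.84 for mitochondrially encoded (median −0.0589), 0.107 for microglial and 0.0566 for SMN complex genes. It was 0.345 for blood (median 0.208, turned in sign) and 0.134 for motor neuron genes without lumbar WT replicate 1, and 0.217 for astrocyte and 0.13 for SMN complex genes without lumbar WT replicate 2. The motor neuron median shrank to −0.0565 without lumbar TKO replicate 1 and −0.0908 without lumbar WT replicate 1. The SMN complex median was −0.102 without lumbar WT replicate 2 and −0.0571 with the mitochondrial share as a covariate. The motor neuron members with the smallest p were Vipr2 (log2 −0.91) and Chodl (−1.06), at adjusted p of 0.824 and 0.843. The test called 7 genes in all, 3 higher and 4 lower, of which 4 lie within 10 Mb of Mir34a. At an unadjusted p under 0.05 there were 972 genes, against 853 expected with no effect (median SE 0.239). Calls numbered 1 without lumbar WT replicate 2, 2 and 3 without thoracic TKO replicates 1 and 2, 4 without either thoracic WT library and 5 or 6 without any other. Igf1, Lum and Zfp981 passed in none of these 8 fits, Masp2 in 5 and Zfp982 in 7.

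In the thoracic cord, Igf1 fell from 22.2 ± 0.249 to 5.02 ± 0.196 CPM (SD, n = 2; log2 −2.15, SE 0.208, adjusted p = 0.0149). Padi2 rose by 1.23 (SE 0.148, adjusted p = 0.0439), Masp2 by 3.93 (SE 0.329, 0.00641), Samd11 by 3.22 (SE 0.372, 0.0394) and Zfp981 by 1.78 (SE 0.207, 0.0394; −0.01 in exon-based RPKM). Zfp982 fell, with 1 read in TKO and 224 in WT (ratio 206, 36.6 to 8170, adjusted p = 0.00641). Oligodendrocyte genes rose with a median of 0.556 and 15 higher when adjusted over the list alone (camera adjusted p = 9.97e-08, adjusted p = 0.103 with an estimated correlation). Klk6, at 69.0 ± 10 CPM in TKO and 29.6 ± 0.756 in WT, had an adjusted p of 0.0851. Microglial genes rose (median 0.418, adjusted p = 0.00015, adjusted p = 0.325 with an estimated correlation; 10 higher and 1 lower when adjusted over the list alone). Astrocyte genes rose as well (0.478, adjusted p = 0.000332, adjusted p = 0.397 with an estimated correlation; 8 higher when adjusted over the list alone). Fibroblast genes fell, 20 of 20 below 0 with a median of −1.30 (adjusted p = 1.94e-08, adjusted p = 0.567 with an estimated correlation; 11 lower when adjusted over the list alone). Cell cycle genes fell with 27 of 29 below 0 (median −0.70, adjusted p = 2.35e-07, adjusted p = 0.688 with an estimated correlation; 4 lower when adjusted over the list alone; median −1.07 without thoracic TKO replicate 1).

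Inhibitory genes fell in the thoracic cord (median −0.502, −0.329 without thoracic TKO replicate 2, 1 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.00268, adjusted p = 0.325 with an estimated correlation). The GABA-synthesising enzyme Gad2 (log2 −0.72) and the receptor subunit Gabra5 (−0.86) had adjusted p of 0.17 and 0.192 over all genes. Glutamatergic genes fell too (−0.344, adjusted p = 0.0185, adjusted p = 0.648 with an estimated correlation; 1 higher and 2 lower when adjusted over the list alone). At the preset correlation ribosomal protein genes rose (0.322, 37 of 48 above 0, adjusted p = 0.000896). Blood (−0.863, 0.0108), mitochondrially encoded (−0.72, 0.0172) and muscle genes (−2.04, 0.0209) fell. All 4 of these had an adjusted p = 0.771 with an estimated correlation. Adjusted over the list alone, 4 blood genes were lower, 0 ribosomal protein and mitochondrially encoded genes passed, and the 1 muscle gene that passed, Pygm, was higher (log2 1.09). Mitochondrially encoded and muscle genes had adjusted p of 0.376 and 0.0977 with the mitochondrial share as a covariate, and of 0.393 and 0.191 without both TKO replicate 2 libraries. Strain markers fell (−0.337, adjusted p = 0.0126, adjusted p = 0.325 with an estimated correlation; 0 passed when adjusted over the list alone). Without thoracic TKO replicate 1 calls were lost for ribosomal protein (adjusted p = 0.739), glutamatergic (0.253) and strain genes (0.122), and without thoracic TKO replicate 2 for mitochondrially encoded (0.494, median −0.276) and muscle genes (0.148). Mitochondrially encoded (0.462, median −0.109) and muscle genes (0.374, median −0.0631) also lost theirs without thoracic WT replicate 1, as did blood and glutamatergic genes without thoracic WT replicate 2 (both 0.0649). The test called 6 genes, 4 higher and 2 lower, 5 of them within 10 Mb of Mir34a, while 3396 genes had an unadjusted p under 0.05. Without lumbar TKO replicate 1 or 2 there were 10 and 11 calls, without either lumbar WT library there were 2, and 1 call was left without thoracic WT replicate 2. Without thoracic TKO replicate 1, thoracic TKO replicate 2 or thoracic WT replicate 1 edgeR called 0 genes, with 3350, 1385 and 1022 at an unadjusted p under 0.05. Zfp982 passed in 5 of these 8 fits, Masp2 in 4, and Igf1, Padi2, Samd11 and Zfp981 in 2 each.

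Whether the genotype effect differed between segments was tested directly. The 1 gene called was Gm42416 (chromosome 18, 36952741 to 37840200), named here after its values were seen, which had 0 reads in both lumbar TKO libraries and 143 to 223 in each of the other libraries (interaction adjusted p = 0.0146). It was at least 112-fold lower in lumbar TKO than in lumbar WT, against a floor of 3 reads over the group. None of its 1099 reads was uniquely placed, and its model spans 77 genes, 58 of them protocadherins. The named genes with the smallest p were Tspo, a mitochondrial membrane protein of microglia, Fam177a, Gemin4, Hoxd3 and Prn, all with an adjusted p of 0.852. Tspo had means of 1.26 ± 0.759 CPM in lumbar TKO, 2.52 ± 0.627 in lumbar WT, 1.87 ± 0.369 in thoracic TKO and 0.539 ± 0.112 in thoracic WT (SD, n = 2). Only 1.38%, 4.24%, 15.9% and 41.3% of the reads of Fam177a, Gemin4, Hoxd3 and Prn were uniquely placed. Ribosomal protein genes had a higher genotype effect in the thoracic cord in 46 of 48 cases (median difference 0.508, camera adjusted p = 5.01e-11, adjusted p = 0.44 with an estimated correlation). In all, 9 lists were called at the preset correlation, 6 higher and 3 lower, and 0 with an estimated correlation. In each of the 9 lists 0 members passed when adjusted over the list alone. Ribosomal protein genes kept their call in all 8 fits that leave out 1 library, and the other 8 lists lost theirs in some. At an unadjusted p under 0.05 there were 597 genes, fewer than the 853 expected with no effect. The test called 2 genes without thoracic TKO replicate 1 or thoracic WT replicate 2, and with edgeR 0 without thoracic TKO replicate 2 or thoracic WT replicate 1 (590 and 184 at an unadjusted p under 0.05).

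Igf1 and Zfp982 were lower and Masp2 and Zfp981 higher in TKO in the test of each segment, 2 shared calls in each direction where independent lists would share 0.000469 and 0.000703. Across 17067 genes, which are not independent replicates, the lumbar and thoracic log2 changes, which share no library, had a Pearson correlation of 0.451 and a Spearman correlation of 0.452. Their covariance was 0.122, and 65.7% of genes had the same sign. The correlation was 0.171 without lumbar TKO replicate 2 (Spearman −0.0175), 0.286 without lumbar WT replicate 2 (Spearman 0.231), and 0.262 without both TKO replicate 2 libraries (Spearman −0.013).

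Thoracic against lumbar cord checked the dissection. Caudal Hox genes, which set the identity of the lumbar levels, were lower in the thoracic cord of both genotypes. Hoxd11 (chromosome 2), Hoxc11 (chromosome 15), Hoxa11 (chromosome 6) and Hoxc13 (chromosome 15) had 258, 258, 227 and 100 reads in lumbar WT and 0 in thoracic WT. They were at least 91.4-, 91.4-, 80.4- and 35.4-fold lower against a floor of 3 reads over the group (adjusted p = 0.00347, 0.00606, 0.00347 and 0.0139). In TKO they were at least 79.1-, 74.9-, 75.9- and 66.7-fold lower (adjusted p = 0.00353, 0.00588, 0.00351 and 0.00429). Hoxd10 had 1263 lumbar and 10 thoracic reads in WT (ratio 134, 72.7 to 281) and 931 and 1 in TKO (ratio 913, 164 to 36100). The antisense Hoxa11os, which cannot be told from Hoxa11 without strand, was at least 34.4-fold lower in WT and had a lumbar over thoracic ratio of 92.2 in TKO (16.2 to 3680). All 8 tested genes of the list had medians of −8.07 in WT and −9.61 in TKO as fitted, and −5.74 and −6.14 with the 5 genes at 0 set to their bounds (camera adjusted p = 7.8e-35 and 1.51e-61, adjusted p = 0.0143 and 0.00462 with an estimated correlation). The test called 7 genes in WT, all lower, and 8 in TKO, 7 lower and 1 higher, Gm42416. At an unadjusted p under 0.05 were 760 genes in WT and 240 in TKO, both fewer than the 853 expected with no effect. WT calls numbered 11 without lumbar TKO replicate 2 and 4 without lumbar WT replicate 2, and TKO calls 5 without thoracic TKO replicate 1.

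Schwann cell genes fell from lumbar to thoracic cord at the preset correlation, with medians of −2.24 in WT and −1.61 in TKO (camera adjusted p = 4.77e-05 and 0.000135, adjusted p = 0.56 and 0.693 with an estimated correlation). The myelin protein genes Pmp2 (log2 −3.19 in WT, adjusted p = 0.563) and Pmp22 (−2.44, 0.807) led the list, and 6 members were lower in WT when adjusted over the list alone. Muscle genes rose toward the thoracic cord (2.06 and 0.948, adjusted p = 4.19e-06 and 0.00403, adjusted p = 0.56 and 0.693 with an estimated correlation), with 8 higher and 1 lower in WT when adjusted over the list alone. In WT, ribosomal protein genes (−0.334, 45 of 48 below 0, adjusted p = 3.88e-09), motor neuron genes (−0.284, 0.00036) and endothelial genes (−0.348, 0.000765) were lower in the thoracic cord, all with adjusted p = 0.56 with an estimated correlation. Nuclear respiratory chain genes were lower too (−0.2, adjusted p = 0.00036, adjusted p = 0.656 with an estimated correlation). Prph, a neurofilament-type protein of motor neurons, had a log2 value of −1.16 (adjusted p = 0.439). In TKO, oligodendrocyte genes were higher in the thoracic cord (0.21, adjusted p = 2.27e-07, adjusted p = 0.0565 with an estimated correlation), as were ribosomal protein genes (0.195, 3.73e-05, adjusted p = 0.693 with an estimated correlation) and microglial genes (0.196, 0.00305, adjusted p = 0.519 with an estimated correlation). Further lists passed at the preset correlation: in WT sex-linked (0.44, adjusted p = 0.0254), ependymal (0.211, 0.0258), inhibitory (0.242, 0.0285) and glutamatergic genes (0.16, 0.0423) were higher in the thoracic cord. Their adjusted p was 0.6, 0.56, 0.56 and 0.569 with an estimated correlation, and with the mitochondrial share as a covariate 0.0529 for both ependymal and glutamatergic genes. Glutamatergic genes had 0.0596 without both TKO replicate 2 libraries. In TKO cholesterol genes were higher (0.113, adjusted p = 0.0192, adjusted p = 0.693 with an estimated correlation) and fibroblast genes lower (−0.199, adjusted p = 0.0213, adjusted p = 0.838 with an estimated correlation). With the covariate the adjusted p in TKO was 0.107 for cholesterol, 0.129 for fibroblast and 0.107 for muscle genes. Adjusted over the list alone, 8 caudal Hox genes were lower in each genotype, 1 motor neuron gene lower in WT, and 1 Schwann gene lower and 1 muscle gene higher in TKO. Of the other called lists, apart from the Schwann and muscle lists in WT, 0 members passed. In WT the caudal Hox, ribosomal protein, muscle and Schwann calls held with each library left out. The highest adjusted p of the others was 0.107 for endothelial, 0.154 for ependymal, 0.163 for both glutamatergic and inhibitory, 0.186 for motor neuron and 0.0513 for respiratory chain genes, each without thoracic WT replicate 2. It was 0.362 for sex-linked genes without thoracic WT replicate 1, where the muscle median was 0.421. In TKO the caudal Hox and oligodendrocyte calls held. The highest adjusted p was 0.917 for cholesterol (median −0.0665), muscle (−0.374) and ribosomal protein genes (0.00372) without thoracic TKO replicate 1. It was 0.921 for fibroblast (median 0.0823) and 0.602 for Schwann genes (0.0406) without lumbar TKO replicate 2, and 0.34 for microglial genes without lumbar TKO replicate 1.

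Loss of a microRNA can raise transcripts that carry its sites, which was asked of 15016 protein-coding genes with a 3' UTR (98.8% of those tested). Of these, 897 had an 8mer match CACTGCCA, 1672 a 7mer CACTGCC and 920 a 7mer ACTGCCA as their best site, 3489 in all, and 11527 had none. Genes with a site had longer UTRs (median 2280 against 923 bases). Their median log2 change over both segments was 0.00649 above that of genes without a site, where UTR length alone gave −0.0629, so that they lay 0.0694 above length-matched genes (p = 0.0001, the smallest that 10000 permutations can give). The 200 control heptamers gave a median shift of 0.0791 (middle 95% 0.0285 to 0.124), and 127 of them were as high as the seed (two-sided p = 0.736 from the exact rank among the controls). Genes with an 8mer site had a shift of 0.107 against a control median of 0.0779 (exact rank p = 0.438). In the lumbar cord the shift was 0.0369 against 0.0309 (exact rank p = 0.677), and in the thoracic cord 0.111 against 0.134 (p = 0.687). The seed shift was 0.0199 with the mitochondrial share as a covariate and 0.0276 without both TKO replicate 2 libraries. On data simulated with a known shift of 0.05 or 0.1, the permutation test detected it in 100% of 40 sets. In these sets values were shuffled within length bins, which removes the shift that the controls share. The comparison with control heptamers was not simulated, so the sets do not show what release would stand out from the controls.

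**Figure D5:**
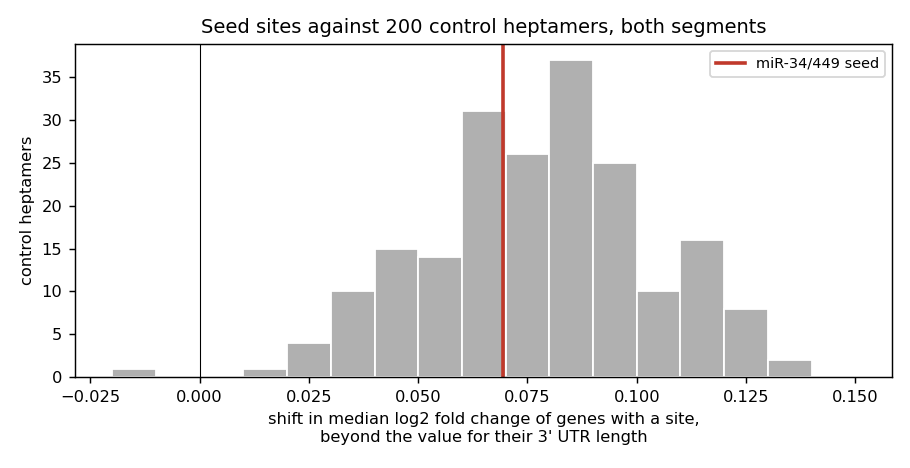
Histogram of the length-matched shift in log2 fold change (TKO over WT, both segments) of genes with a site for each of 200 control heptamers, with the miR-34/449 seed as a red line. The seed lies at 0.0694, inside the control range, with 127 controls as high.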

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

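All tests of explanations in this part were chosen after the result was seen, except the test of maturation genes, which was written down before its result.

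The genotype effect differed between the thoracic and lumbar cord for 10 results, by the test of the difference itself, at the preset correlation for the 9 gene lists. Ribosomal protein genes had an adjusted p of 5.01e-11 (median difference 0.508), nuclear respiratory chain genes one of 0.00144 (0.285) and Gm42416, with 0 reads in both lumbar TKO libraries, one of 0.0146. Ependymal and motile cilia (−0.385), glutamatergic (−0.313), motor neuron (0.271) and oligodendrocyte genes (0.258) each had an adjusted p of 0.0204. Inhibitory (−0.258) and microglial genes (0.227) had an adjusted p of 0.0375, and endothelial genes one of 0.0454 (0.152). Single libraries moved these median differences. The motor neuron one was 0.0551 without thoracic TKO replicate 1, and the ependymal one −0.142 without lumbar TKO replicate 1. The glutamatergic one was −0.118 without lumbar TKO replicate 1 and −0.488 without lumbar TKO replicate 2. With an estimated correlation the adjusted p was 0.44 for the ribosomal, ependymal, glutamatergic, oligodendrocyte, inhibitory and microglial lists and 0.715 for the respiratory chain, motor neuron and endothelial lists. With the mitochondrial share as a covariate, calls were lost for endothelial (0.105), motor neuron (0.0766), oligodendrocyte (0.075), ependymal (0.0613) and glutamatergic genes (0.0507). Without both TKO replicate 2 libraries they were lost for ependymal (0.218) and oligodendrocyte genes (0.0567), and the endothelial call was also lost with the replicate block (0.0661). With 1 library left out, the ribosomal call held in all 8 fits and the respiratory chain call in 7 (adjusted p = 0.443 without thoracic TKO replicate 1). Glutamatergic and motor neuron genes kept theirs in 5 (0.202 and 0.466 without the same library), ependymal and oligodendrocyte genes in 4 (0.105 without thoracic TKO replicate 2 and 0.272 without thoracic WT replicate 2), endothelial and inhibitory genes in 3 (0.508 without thoracic TKO replicate 1 and 0.138 without thoracic WT replicate 2) and microglial genes in 2 (0.138 without thoracic WT replicate 2). Groups of 2 libraries are too small for a test of outlying samples.

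Calls between TKO and WT crowd around Mir34a on chromosome 4, among them Masp2, Padi2, Samd11 and the zinc finger genes. Genes 1 to 10 Mb from Mir34a were called with an odds ratio of 19.4 (8.63 to 39.5), which argues against a local effect of the deletion as the whole source. With unique reads 11 of the 11 genes stayed called, which argues against reads shared between zinc finger copies of the reference genome as the whole source. Reads were placed on mm10, so copies that differ from it or are absent from it could not be examined. Flanking DNA from another strain, carried along with the targeted allele, is a candidate explanation. At 2 to 10 Mb, where 4 genes were higher and 5 lower, the odds ratio was 20.3 (8.61 to 42.6). Both intervals take genes as independent, which neighbouring genes are not, so they are too narrow. Whether any of these genes responds to loss of the microRNAs stays open, because in this design the deletion and its flanking DNA go together.

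Glial genes lay higher and fibroblast and cell cycle genes lower in TKO. The low mitochondrial and high intron share of the TKO replicate 2 libraries does not account for it at the preset correlation, where 5 of the 5 lists kept direction and call with the mitochondrial share in the model and without these libraries; the cell cycle median moved from −0.713 to −0.481, and with an estimated correlation none of the 5 was called even with all libraries (adjusted p 0.0729 to 0.323). Fewer non-neural cells in the TKO dissections would raise all neural genes alike. Glial genes lay 0.442 above neuronal genes (SE 0.0646 over genes). Per library the difference was 0.462 (SE 0.0194 over libraries, 0.447 to 0.476 with each left out). Its sign and size reflect the lists chosen, since the glial lists had been called higher and the inhibitory list lower in these data. Neither SE covers that choice, so the gap cannot decide whether there were fewer non-neural cells. Neural lists not called had medians of 0.108 (oligodendrocyte precursor), 0.0868 (synaptic vesicle), 0.0608 (potassium and sodium channels) and 0.0433 (neurofilament). Those of motor neuron and glutamatergic genes were −0.0536 and −0.199. The gap was smaller in the lumbar cord (TKO 0.138 and 0.0805, WT −0.158 and −0.206) than in the thoracic (TKO 0.347 and 0.362, WT −0.271 and −0.283). For the fibroblast part, 1 of 3 other non-neural lists had a median under −0.5 (muscle −1.22, Schwann −0.454, endothelium −0.109). Muscle lay at −0.389 without thoracic WT replicate 1. Blood, outside this tally, lay at −0.836 over genes going both ways. With the mitochondrial covariate camera called Schwann (adjusted p = 0.000908) and blood genes (4.66e-06) lower, not muscle (0.339) or endothelium (0.735). Fewer meninges and fewer meningeal transcripts per cell cannot be told apart. A later stage of maturation stays open. Immature neural genes had a median of −0.152 (15 of 24 below 0, camera p = 0.0285, and p = 0.107 with an estimated correlation). The largest fall among them was that of H19 (−2.32), a fetal growth-associated RNA. Mature genes had a median of 0.33 (9 of 9 above 0, camera p = 0.000115, and p = 0.0274 with an estimated correlation). Most mature genes, such as Cryab, Pllp and Car2, are themselves glial, so this list cannot separate maturation from the glial rise. Its neuronal members Camk2a and Thy1 had log2 values of 0.287 (SE 0.204) and 0.191 (SE 0.16). Chance is not excluded, since 2 of the 35 splits of the 8 libraries into 4 and 4 called as many genes. This counts called genes of any kind, not the pattern itself. The real split called 119 with segment as a term. The highest, 1131, came from lumbar TKO replicate 1, both lumbar WT libraries and thoracic WT replicate 1 against the rest. That split is not independent of genotype, since most WT libraries lie on one side and most TKO libraries on the other. Within each segment it also follows the mitochondrial share. In the lumbar cord 12%, 10.5% and 12.4% stand against 4.99%, and in the thoracic cord 16.8% against 11.9%, 6.53% and 9.45%. Other reasons for its count were not tested. The next highest, with 12, was lumbar against thoracic cord. This split is the same as the segment term and cannot be fitted beside it, so its count is not comparable with the others. For the glial and neuronal difference, 2 of 36 within-segment relabellings were at least as large, the real labelling and its mirror image with TKO and WT exchanged. In each segment both TKO libraries lay above both WT libraries, so no other relabelling could be as large. A count of 2 is the smallest that this test can give, so it cannot exclude chance with so few libraries.

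Genes with a miR-34/449 seed site lay 0.0694 above length-matched genes without one. Release of targets by more than the spread of the controls is argued against, since 127 of the 200 control heptamers gave a shift as high. A bias of UTR base composition is a candidate explanation, as 199 of the 200 controls lay above 0. A release smaller than the spread of the controls, or limited to a few targets, stays open.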

How the results depend on the processing

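Exon counts, mitochondrial settings, the fits without both TKO replicate 2 libraries or without genes near the deleted loci, and crossed numbers were chosen after the data had been seen. Counts of called genes follow in the order lumbar, thoracic, both segments, difference of effects, segments in WT and segments in TKO, where the main values were 7, 6, 61, 1, 7 and 8. RLE and upper-quartile scaling, limma-voom, a mean of 10 reads, and leaving out sex-linked and red-cell or mitochondrial genes kept every count within 1.5 times. Over comparisons, 79 values moved and 115 stayed: counts within 1.5 times, the correlation between segments within 1 SD of its leave-one-out values, and the seed shift in direction and side of its permutation test. In size the seed shift went from 0.0694 to 0.0199 with the mitochondrial covariate, 0.0276 without both TKO replicate 2 libraries, 0.0312 on intron reads and 0.107 for 8mers. DESeq2 called 41 (22 higher, 19 lower), 416, 640, 2, 21 and 17, and edgeR with no filter 17, 65, 310, 1, 11 and 14. Unique gene reads gave 104 for both segments and 0 for the difference (565 at an unadjusted p under 0.05). Limma on RPKM gave 1, 2, 6 and 0 (530 unadjusted for the difference, where 853 were expected with no effect). Total exon reads gave 2 lumbar, 12 over both and 0 for the difference (539 unadjusted), and unique exon reads 2, 24 and 0 (535 unadjusted), with 4 and 4 between segments. Fits of only 4 libraries called 23 thoracic genes and 19 between segments in WT. The mitochondrial share as a covariate gave 193, 1248, 720, 144, 39 and 21, and leaving out both TKO replicate 2 libraries 16 lumbar, 13 thoracic and 16 between segments in WT. Without genes near the deleted loci 3 lumbar and 1 thoracic gene remained called. Zfp981 changed sign on the RPKM scale, at −0.118 lumbar, −0.00734 thoracic and −0.0628 over both (adjusted p 0.958, 0.986 and 0.641), where intron reads are not counted. Other causes were not tested. Of the settings of single named genes, 775 kept direction and call, 263 kept the direction and lost the call and 3 changed sign.

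Leaving out 1 library at a time gave 1 to 6 lumbar calls (1 without lumbar WT replicate 2), 0 to 11 thoracic (0 with edgeR without thoracic TKO replicate 1, where 3350 genes had an unadjusted p under 0.05; 11 without lumbar TKO replicate 2), 7 to 194 over both (7 without lumbar WT replicate 2, 194 without lumbar TKO replicate 1), 0 to 2 for the difference (0 with edgeR without thoracic TKO replicate 2 or thoracic WT replicate 1, with 590 and 184 unadjusted), 4 to 11 between segments in WT and 5 to 11 in TKO. Gene lists called over both segments ranged from 8 to 13, the correlation between segments from 0.171 (without lumbar TKO replicate 2) to 0.55 and the seed shift from 0.0459 to 0.0989. Called lists that kept their call in each of the 8 fits numbered 8 of 11 over both, 4 of 11 lumbar, 6 of 12 thoracic, 1 of 9 for the difference, 4 of 11 between segments in WT and 2 of 8 in TKO. In some fit the median moved by over 1.5 times for 4, 8, 7, 8, 6 and 6 of them, and turned in sign for 1 lumbar list and 4 between segments in TKO. A lone library left in a group is assumed to vary like the other groups. Where camera called 11 lists over both segments, it called 0 with an estimated correlation (6 at an unadjusted p under 0.05) and fry called 6; 17 were called without both TKO replicate 2 libraries. The correlation was 0.262 without those libraries.

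The labels do not say what the replicate numbers mean, and they were not used to pair libraries, since deviations of same-numbered libraries correlated from −0.33 to 0.442 between groups. The correlation between lumbar and thoracic was 0.442 in TKO and −0.208 in WT. It was also 0.442 between lumbar TKO and thoracic WT, which cannot share a mouse. The TKO value therefore cannot tell whether the 2 TKO libraries of a number share a source, which stays open. With the replicate block the counts were 11 thoracic, 222 over both, 18 between segments in WT and 19 in TKO, and it changed no other count by over 1.5 times. Of the lists, the block ended the calls of endothelial genes for the difference (adjusted p 0.0661) and of glutamatergic (0.0845) and inhibitory genes (0.0517) between segments in WT, and added endothelial (0.0443) and Schwann genes (0.0471) in the lumbar cord, muscle (0.0331) and sex-linked genes (0.0471) for the difference and blood (0.0317) between segments in TKO. The block as a random effect gave 28 over both, and libraries of one genotype and number summed gave 9. With the WT numbers crossed, chosen after the data had been seen, summed libraries gave 2 and the block 379 between segments in WT. Depth limits genes near the floor of 0.153 to 0.174 CPM per library.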

Other observations

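The genes described first in this part were chosen after their values were seen, and the tests here were not planned. They are single genes, and no list of such genes was tested for enrichment. In TKO over both segments, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called as lower Postn, a matricellular protein (log2 −1.43, SE 0.219, adjusted p = 0.0375), Mfap5 of microfibrils (−1.45, SE 0.207, 0.0346), the collagen Col14a1 (−1.41, SE 0.204, 0.0346), the protease Adamts12 (−1.02, SE 0.155, 0.0375), the proteoglycan Gpc3 (−1.18, SE 0.188, 0.0437) and Dpp4, a peptidase of fibroblast progenitors (−1.42, SE 0.195, 0.0285). Ear6, a second eosinophil-type ribonuclease beside Ear1, fell by 3.72 (SE 0.539, adjusted p = 0.0346).

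Other single genes chosen after their values were seen were called as higher. Gpd1, the glycerol phosphate dehydrogenase of oligodendrocytes, rose by 1.06 on the log2 scale (SE 0.144, adjusted p = 0.0276), Car14, a carbonic anhydrase, by 0.88 (SE 0.111, 0.0227), Acot11, an acyl-CoA thioesterase, by 0.62 (SE 0.103, 0.0493), and Cyp2d22, a cytochrome P450, by 0.81 (SE 0.123, 0.0375). Of the genes of neural maturation, H19, a fetal growth-associated RNA, had a log2 value of −2.32 (adjusted p = 0.0573), Cryab, a small heat shock protein of mature glia, 0.81 (0.0573), Nrep, a protein of developing neurons, −0.93 (0.0765) and Fabp7, the fatty acid binding protein of radial glia, −0.91 (0.141). The growth cone genes Gap43 and Dpysl3 had log2 values of −0.43 and −0.55 (adjusted p = 0.115 and 0.103).

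The first principal component took 41.4% of the variance of log2 CPM and the second 17.3%. On the first, the TKO replicate 2 libraries scored 43.5 and 44.8 and thoracic WT replicate 1 scored −55.0. Among the 9 pairings of a lumbar with a thoracic split, the correlation of genotype effects (0.472 in size on this scale) was the second highest, and the highest other was 0.536.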
